A study of Pseudomonas putida KT2440 and Pseudomonas putida DOT-T1E with 12 samples.

How the data were processed

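RNA-seq libraries of Pseudomonas putida KT2440 and T1E were compared within each strain, in 3 groups of 2 libraries (glucose, toluene vapor and shock). Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. The aligner, counter, annotation and genome build are not given in the sources used here, and coordinates are those of the authors' tables.

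The authors deposited 1 table per strain, with a row per annotated gene and strand and rows for predicted transcripts. For KT2440 the deposited columns headed raw counts hold signal, that is coverage summed over bases, not reads: the values show that 1 read of 100 bases adds 100. All other value columns are scores. Per the file headers these are the authors' normalized, RPKM and expression scores, rounded to whole numbers by the authors, with expression being signal scaled by 1 factor per library and divided by row length. The T1E table holds the authors' expression scores without the signal, so the score of 1 read was recovered for each T1E library from the steps between low values. Tested on KT2440, where it is known, that method was off by -2.0 to -2.4%. Deposited p-values and q-values in the authors' deposited table compare the 2 libraries of a group with each other. By those, 1003, 846 and 301 of 5350 KT2440 genes and 574, 247 and 263 of 5721 T1E genes differed at q below 0.05 between the glucose, vapor and shock libraries, and they were not used further.

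Signal was divided by 100 to give read equivalents. Since the tables hold no read counts, count models do not apply, and limma was used as written for normalized values before the data were examined. Annotated protein-coding rows were tested on log2(expression + 1) with the authors' scaling, a mean expression of at least 10, and limma's trended, robust moderation over the 6 libraries of a strain. Rows of rRNA, tRNA, other RNA and predicted transcripts stayed out of that test.

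Because signal was found on the strand opposite the genes, a further set of features was built after the data were seen. Predicted transcripts that lie opposite protein-coding genes only were merged where they share a gene, which gave 109 loci over 128 genes in KT2440 and 593 loci over 730 genes in T1E. Their read equivalents were scaled by median of ratios and tested by limma on log2(value + 1) at a mean of 10 or more, with Benjamini-Hochberg adjustment at 5%, two-sided. A fold change on this scale understates the change of low loci. The design written beforehand asked for trended and robust moderation. Trend without robust was used for both strains, because the robust fit gave far smaller p-values at some KT2440 loci. Whether its prior was unstable was not tested. That choice was made after the counts of calls under all 4 combinations of trend and robust had been seen, and the other 3 are given in the closing section. Loci that hold several genes cannot tell these genes apart.

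Genes were named by a rule fixed before the data were examined and then applied to loci. Per comparison it takes up to 8 rises and 8 falls past 5% with a mean of 50 or more read equivalents and groups that do not overlap, up to 4 members of each of 24 fixed gene lists, and a fixed set of solvent and stress genes. Names outside it are marked in the text. Lists with at least 3 loci (5 in KT2440, 15 in T1E) were tested by limma camera with a preset correlation of 0.01, and again with an estimated correlation and with fry. No list call held with the estimated correlation.

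Simulated libraries with known changes were passed through the same steps for the vapor comparison. Over 107 KT2440 loci with 20 changed, 45% of 2-fold, 97.8% of 4-fold and 100% of 8-fold changes were called, with 4.2 false calls per 100. Over 577 T1E loci with 100 changed, the shares were 86.5, 99.2 and 99.7%, with 4.9 false calls per 100. The 2 libraries of every group differed by more than counting noise, with chi-square per degree of freedom from 3.1 to 53.0 over loci, so none was treated as a duplicate. This excess differed between groups, at 53.0 in KT2440 glucose and 12.3 in KT2440 vapor. The simulated shares and false calls therefore hold for the spread that was set, and do not give the error rate of the calls below.

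Alternatives changed the scaling, pseudocount, filter, features, libraries in the fit, replicate block, moderation and threshold, and left out each library in turn. For named loci, other scalings were run as they stand and also moved to the median of the reported scaling. Work used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.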

Results

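RNA was sequenced from 12 libraries of 2 strains of Pseudomonas putida, a soil bacterium. The labels describe KT2440 as toluene-sensitive and T1E (DOT-T1E) as toluene-tolerant. Each strain had 3 groups of 2 libraries. They were a glucose control, toluene in the vapor phase and a shock, which the sample labels call a toluene shock and the series design text calls a butanol shock. The comparisons ask how each strain's transcripts changed under the vapor and under the shock, and whether the strains differed. Signal equal to 4398805 reads of 100 bases or more was present in each KT2440 library, and to 3036120 or more in each T1E library. Ribosomal RNA took 96.17 to 97.53% of it in KT2440. In T1E that share was 77.15 and 79.44% in the glucose libraries, 67.6 and 63.24% in the vapor libraries and 61.17 and 68.35% in the shock libraries, so it moved with the groups. The T1E share of tRNA moved too, from 0.47 and 0.478% in glucose to 0.689 to 2.245% in treated libraries, as did that of annotated protein-coding rows, from 0.396 and 0.436% to 1.343 to 1.91%. The ratio of loci signal to those rows was lower in every treated library of both strains, at 3.5 to 6.8 against 8.0 and 10.5 in KT2440 and 6.5 to 8.3 against 14.8 and 13.2 in T1E. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries.

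Nearly all signal lay on the strand opposite the annotated genes. Of 116 rRNA and tRNA genes with a predicted transcript opposite them, 115 held more signal opposite. The exception was T1E_5758, annotated as rRNA, with 28003 read equivalents on its annotated strand and 676 opposite. A transcript opposite several genes counts whole for each, as for PP_5SA and PP_23SA, so these genes are not separate observations. At rRNA and tRNA genes 99.86% of the signal lay opposite in KT2440 and 98.88% in T1E. The same held at protein-coding genes with a predicted transcript opposite them, called loci here and named after the gene. These predicted transcripts had a median length of 102 bases in KT2440 and 100 in T1E, so a locus can cover a small part of its gene. The KT2440 locus PP_0168 covers 82 bases between 194467 and 219900, while cmk/rpsA covers 1256 bases. Changes at loci describe the covered bases and not whole genes. In KT2440 108 of 109 loci held more signal opposite than annotated, with a median ratio of 91.3. In T1E 567 of 593 did, with a median ratio of 18.3. These genes were selected for having such a transcript. Summed signal of the loci was 3.5 to 10.5 times that of all annotated protein-coding rows in KT2440 libraries and 6.5 to 14.8 times in T1E. All 33 KT2440 and all 15 T1E loci with ribosomal protein genes were among them. The step at which the strands were exchanged, if they were, is not given in the sources used here. Comparisons below therefore lead with the loci, features chosen after the strand of the signal was seen.

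**Figure D1:**
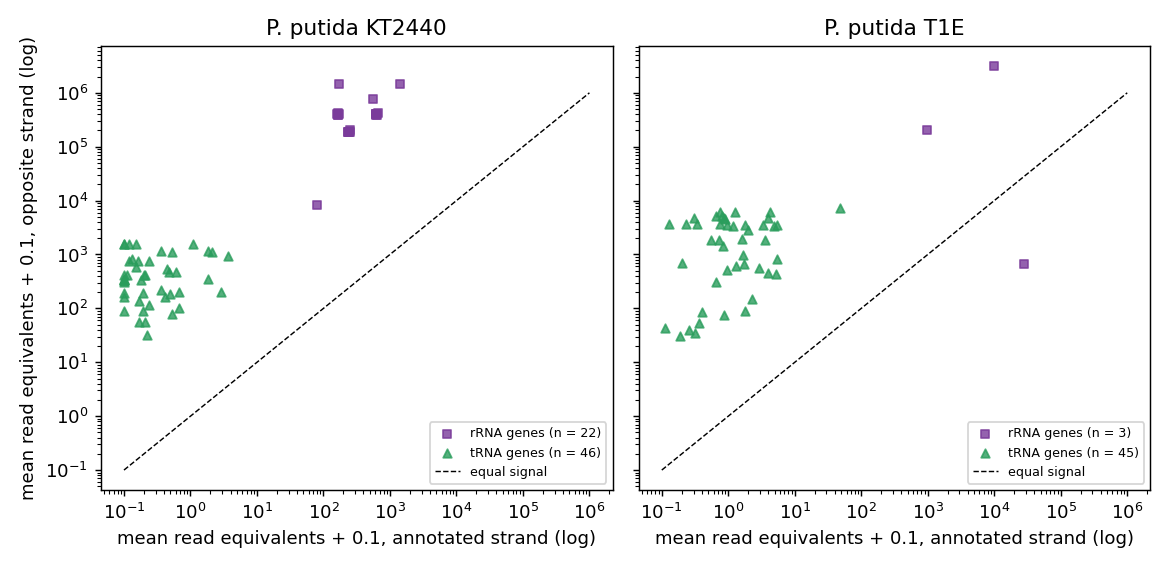
Mean signal of rRNA and tRNA genes in read equivalents on the annotated strand (x axis, log scale) and on the opposite strand (y axis, log scale) in KT2440 and T1E, over the 6 libraries of each strain. Each point is a gene with an opposite predicted transcript, and 115 of the 116 lie above the dashed line of equal signal. A transcript opposite several genes is drawn with its whole signal at each, so points are not separate observations.

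On the annotated strand, no protein-coding gene passed a 5% false discovery rate in any of the 6 comparisons. At a mean of 10 or more read equivalents 11 passed in KT2440 vapor, 13 in KT2440 shock, 1 between these and 3 in T1E vapor, and with scaling to all signal 1 passed in T1E vapor. KT2440 had 3964 genes tested by limma, of which 390 had an unadjusted p below 0.05 for vapor, 408 for shock and 275 between shock and vapor. T1E had 5169 tested, with 536, 566 and 69. These rows held only 4670 to 7666 read equivalents per KT2440 library and 12637 to 105852 per T1E library. In simulated vapor comparisons of these rows, 0% of 8-fold changes were called in KT2440 and 0.3% in T1E, so this test could not detect changes of that size. Genes with the solvent pump symbols ttgA, ttgB and ttgC had no opposite transcript in either strain. Their annotated-strand signal in KT2440 was at most 3.9 read equivalents per library for ttgA, 16.4 for ttgB and 19.0 for ttgC. For ttgA it was 0 and 1 in glucose, 1.9 and 3.1 in vapor and 1.8 and 3.9 in shock. For ttgB it was 1 and 4, then 5.9 and 16.4, then 7.9 and 5, and for ttgC 3.6 and 2, then 3.1 and 19, then 2.4 and 2.6. The solvent pump list had 3 KT2440 rows with a median log2 change of 2.06 in vapor, and did not pass (limma camera adjusted p = 0.526). In T1E the symbol ttgB is on T1E_0107, numbered away from ttgC (T1E_0241) and ttgA (T1E_0243). In KT2440 ttgB (PP_1385) is numbered between ttgC (PP_1384) and ttgA (PP_1386), so T1E_0107 may not belong to the same pump. With the authors' scaling, the log2 change of T1E ttgB was 0.00 ± 0.39 in vapor and -0.37 ± 0.39 in shock (limma adjusted p = 0.679). That of T1E ttgA was 0.12 ± 0.35 and -0.19 ± 0.35. On that scale the median T1E row was at 0.70 in vapor and 0.71 in shock, so both genes lay below the typical row. Since signal elsewhere lay mostly opposite the genes, annotated-strand values may not be those of the pump transcripts. T1E ttgC, at 0 and 4.1 read equivalents in glucose, was at 3.50 ± 1.77 in vapor (adjusted p = 0.555) and 3.31 ± 1.77 in shock (adjusted p = 0.545), with both treated groups above glucose in every library. Ribosomal protein rows in T1E ranked lower than other rows in vapor (camera adjusted p = 0.0404) and shock (adjusted p = 0.000218), not with an estimated correlation (adjusted p = 0.985 and 0.978). Leaving out 1 library gave up to 351 calls in KT2440 and 1336 in T1E, the latter without glucose replicate 2.

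In KT2440 under toluene vapor, the largest changes included rises at petC and PP_3035 and falls at bfr and infA. The locus at petC (PP_1319, cytochrome c1 of the respiratory chain, 1506737 to 1506906) went from 61.1 ± 27.2 scaled read equivalents in glucose to 872.1 ± 203.6 in vapor (SD, n = 2). Its log2 fold change was 3.87 ± 0.37 (SE), with a limma adjusted p of 0.000213. PP_3035, a hypothetical protein, rose by 4.06 ± 0.51 on the log2 scale. Iron storage protein bacterioferritin (bfr, PP_1082) fell by 2.94 ± 0.45, and translation initiation factor IF-1 (infA, PP_4007) fell by 2.54 ± 0.28. In all, 41 of 107 loci passed, 19 higher and 22 lower.

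Other rises in KT2440 vapor were at ribosomal protein genes rpsN (2.62) and rpsH (1.89), at secY/rpmJ (1.44), which includes the secretion channel subunit secY, at crc (1.94) and at dacA (1.96), a cell wall carboxypeptidase. An AhpCTSA-family antioxidant protein gene, PP_1084, rose by 2.29, RNA polymerase subunit gene rpoC by 1.94 and hypothetical PP_1794 by 2.07. The envelope list had 4 loci, of which oprL/PP_1224 (1.18) and oprF (0.77) rose. Falls included PP_5232 (-2.43), PP_4248 (-1.93), PP_0641 (-1.94) and PP_0750 (-1.93), all hypothetical, the MvaT-type regulator PP_1366 (-1.82), ribosomal protein gene rpsT (-1.76), thioredoxin gene trx-2 (-1.29), PP_5234 of the nitrogen list (-1.75) and acyl carrier protein gene acpP (-1.05). Ribosomal protein loci moved both ways, with 3 of 33 higher and 1 lower, the same numbers when adjusted over the list alone, and the list did not pass (limma camera adjusted p = 0.292). None of the 5 heat shock loci passed. Their values were 1.04 at groEL (adjusted p = 0.0656), 0.75 at clpX, 0.54 at groES, 0.30 at clpB and -0.56 at ibpA. Without vapor replicate 2 only 18 loci passed. All changes are relative to the median locus, and with the authors' scaling 11 loci were higher and 32 lower, with scaling to all signal 5 and 35. The rises at secY/rpmJ, oprL/PP_1224 and oprF passed with neither, and those at PP_1084, PP_1794, dacA, crc and rpoC did not pass with scaling to all signal.

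In KT2440 under the shock, all 5 heat shock loci rose relative to the median locus, of which clpB and ibpA also passed under every other scaling. The locus at clpB (PP_0625, a disaggregating chaperone) went from 9.58 ± 1.77 to 251.5 ± 12.1 scaled read equivalents (SD, n = 2), a log2 change of 4.59 ± 0.42 (limma adjusted p = 2.5e-05). The small heat shock gene ibpA (PP_1982) rose by 3.05 ± 0.26, chaperonin gene groEL (PP_1361) by 2.07 ± 0.39, groES by 1.29 ± 0.40 and the protease subunit gene clpX by 1.24 ± 0.31. As a list they passed limma camera (adjusted p = 0.0199) and all 5 passed when adjusted over the list alone, but the list did not hold with an estimated correlation (adjusted p = 0.288). In all, 62 of 107 loci passed, 34 higher and 28 lower.

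Hypothetical gene PP_1833 (2057912 to 2058128) held 697 read equivalents in the shock libraries and 3 in the glucose libraries, a scaled ratio of 362.1 with an exact 95% interval from 123.4 to 1759.9 that covers counting error only. RNA-binding protein gene hfq rose by 3.67, petC by 3.95, PP_3035 by 3.90, crc by 3.14 and dacA by 2.94. Glutamine synthetase gene glnA rose by 2.77, outer membrane gene oprH by 2.07, pqqA of quinone cofactor synthesis by 1.86 and lpdG of 2-oxoacid oxidation by 1.84. Among ribosomal protein loci 3 of 33 rose, including rpsN (2.67) and rpsH (1.72), and 9 fell, including rpsT (-2.70) and PP_5280/rpmG/rpmB (-1.51), and adjusted over the list alone the numbers were 3 and 7. That list did not pass (limma camera adjusted p = 0.196). The lowest values were at PP_5232 (-4.07), infA (-3.63), PP_4248 (-2.81) and bfr (-2.77). PP_3909 (-2.07), PP_4268 (-1.80) and elongation factor gene tuf (PP_0440, -1.75) also fell. Without shock replicate 1 the count was 40, and clpX and groES no longer passed. Relative to the median locus the calls split as given, and they were 15 higher and 54 lower with the authors' scaling, 30 and 40 with upper-quartile scaling and 25 and 40 with scaling to all signal. The calls at groEL, oprH, lpdG and rpsH were lost with the authors' scaling, and those at clpX, groES and pqqA with that and with scaling to all signal.

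**Figure D2:**
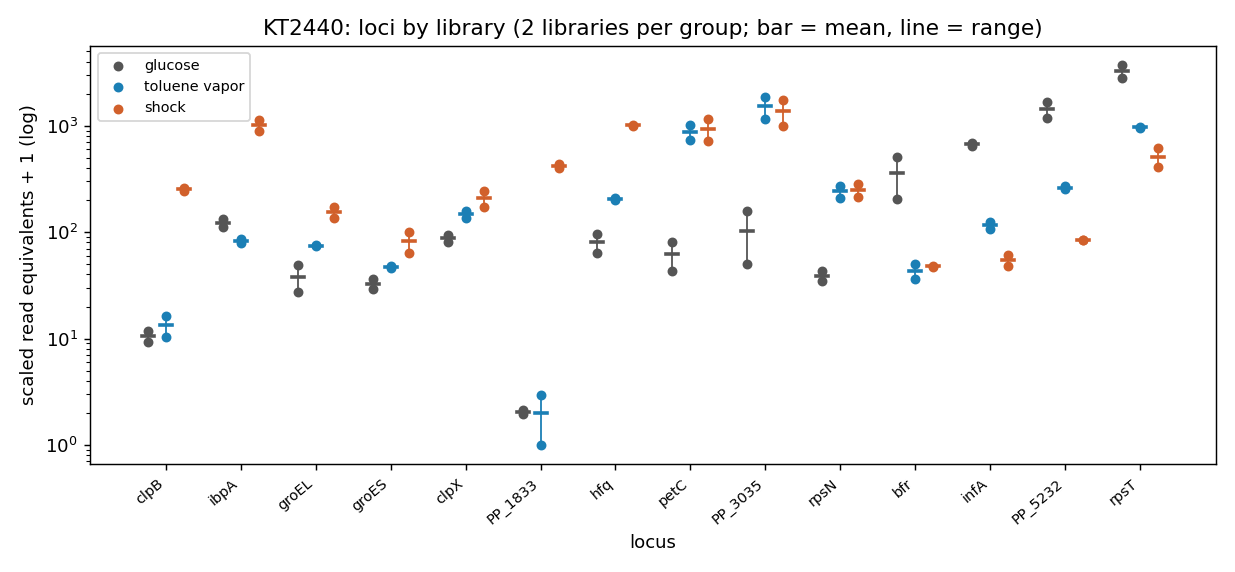
Scaled read equivalents plus 1 (log axis) at 14 KT2440 loci in glucose, toluene vapor and shock, 2 libraries per group, with the bar at the mean and the line over the range. At clpB the shock libraries average 251.5 and the glucose libraries 9.58, while at bfr glucose averages 358.1 and shock 46.7.

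Between shock and vapor in KT2440, the chaperone loci clpB and ibpA were higher in shock, and 4 of 33 ribosomal protein loci were lower. The locus at clpB was higher by 4.29 ± 0.42 on the log2 scale, ibpA by 3.61 ± 0.26 (limma adjusted p = 1.1e-05) and PP_1833 by 7.93, on a scale that depends on the added read at so low a vapor level. Also higher were oprH (2.95), PP_0641 (2.46), hfq (2.30) and glnA (2.02), with pqqA (1.41), lpdG (1.05) and trx-2 (0.97). For the heat shock list 2 of 5 loci passed, 3 when adjusted over the list alone, and camera gave an adjusted p of 0.00252, or an adjusted p = 0.177 with an estimated correlation. Ribosomal proteins had 4 of 33 loci lower, namely PP_5280/rpmG/rpmB (-1.26), rpsU (-0.97), rplU (-1.33) and rplK/rplA (-1.35), and 1 when adjusted over the list alone. That list had a camera adjusted p of 9.22e-08, and an adjusted p = 0.177 with an estimated correlation. PP_5232 (-1.64), tuf (PP_0440, -1.96) and infA (-1.09) were lower too. In all 20 of 107 loci passed, 13 higher and 7 lower, but 41 with only the 4 libraries compared, 42 without either glucose library and 6 to 8 without any 1 vapor or shock library. The split was 7 and 18 with the authors' scaling, 10 and 23 with upper-quartile scaling and 10 and 1 with scaling to all signal. With scaling to all signal none of the 4 ribosomal protein loci passed, nor did PP_5232, infA, glnA, pqqA and lpdG, and with the authors' scaling pqqA, lpdG and trx-2 did not.

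In T1E under toluene vapor, a block of prophage genes rose, and loci such as dnaK, htpG and sucD/sucC/lpdG fell relative to the median locus. The block spans 73 genes from aprD (T1E_1313) to T1E_1385 (1500921 to 1549085), and its limits were set after its values were seen. Of its 21 loci 20 rose, by 1.86 to 3.08 on the log2 scale, with a median of 2.55 over the 21. At T1E_1344, a transcriptional regulator gene, signal went from 30.5 ± 1.26 to 230.6 ± 22.7 scaled read equivalents (SD, n = 2), a log2 change of 2.87 ± 0.24 (limma adjusted p = 0.000163). The exception was T1E_1338, a Cro/CI-family prophage regulator gene, at -0.11 ± 0.19. In all, 202 of 577 loci passed, 96 higher and 106 lower.

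Block loci with large rises were T1E_1385 (2.73), T1E_1374/T1E_1375 (2.71), which includes a putative baseplate gene, T1E_1381 (2.70) and T1E_1379/T1E_1380 (2.63), with tail fiber assembly and terminase genes. T1E_1346/T1E_1347 (2.61) and T1E_1376/T1E_1377/T1E_1378 (2.60) also rose. In the fixed phage list 3 of 5 loci rose, also 3 when adjusted over the list alone, including prophage antirepressor T1E_1342 (2.36) and integrase T1E_4155 (3.01), and the list did not pass (limma camera adjusted p = 0.158). Outside the block the beta-lactamase gene lact-2 (2.48), flagellar gene flhA (2.09) and nuoG of NADH dehydrogenase (1.48) rose. The dnaJ gene T1E_0653 fell by 2.05 ± 0.34, htpG by 1.72 ± 0.22 and dnaK by 1.62 ± 0.20. Of 10 heat shock loci 4 fell, with clpX/clpP/tig at -0.94, also 4 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.158), while clpB was at 0.06 (adjusted p = 0.874). TCA and glyoxylate loci fell at 7 of 13, or 8 when adjusted over the list alone, including sucD/sucC/lpdG (-1.01) and maeB (-0.95). Their camera adjusted p was 0.00688, and the adjusted p = 0.589 with an estimated correlation. Ribosomal protein loci fell at 9 of 15, also 9 over the list alone with 1 higher, including cmk/rpsA (-0.88) and the 28-gene locus from rpsJ (-1.12). Their camera adjusted p was 0.00891, with an adjusted p = 0.589 with an estimated correlation. Also lower were the 9-gene atpI locus, going from 23710 to 11860 scaled read equivalents, and glnA at -1.34, pyrophosphatase gene ppa at -1.45 and aldolase gene fda at -1.39. Further falls were at engA (-1.56), the polynucleotide phosphorylase gene T1E_0634 (-1.51), T1E_0086 (-1.48) and dksA (-0.76). The pump repressor gene ttgR was at -2.24 ± 0.63 (adjusted p = 0.024), and lost its call without either glucose or either vapor library. Leaving out 1 glucose or vapor library left 79 to 128 loci. The authors' scaling gave 40 higher and 225 lower, and scaling to all signal gave 518 higher and 2 lower. With the latter, the falls named here other than ttgR, unlike that at sepA given further below, did not pass or turned into rises.

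**Figure D3:**
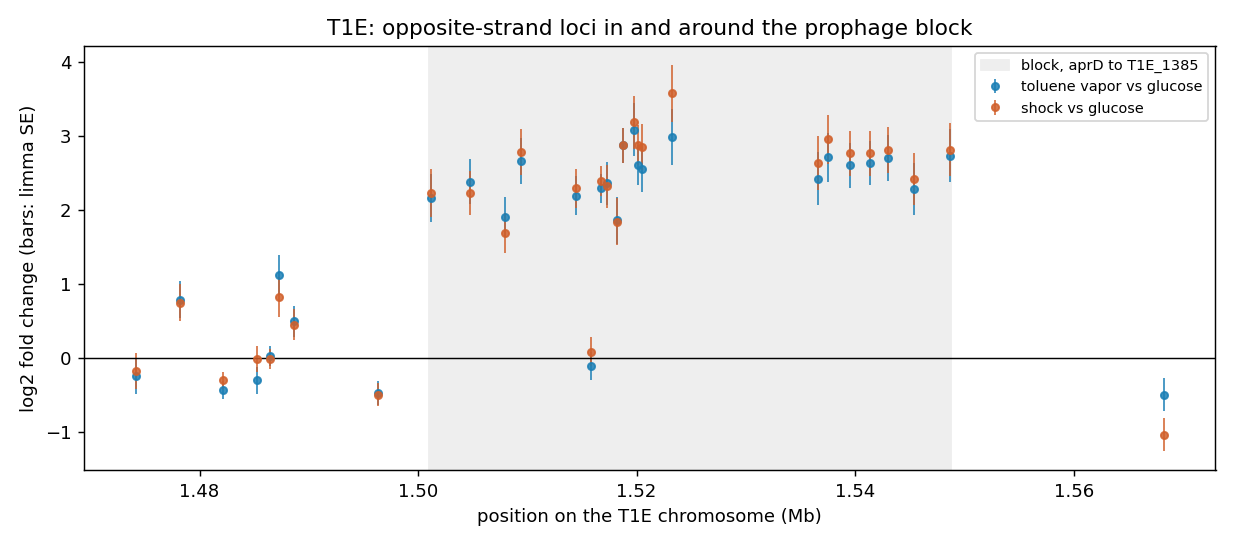
Log2 fold changes (y axis, bars show the limma SE) of T1E loci by position on the chromosome in Mb (x axis) for toluene vapor and shock against glucose, with the block from aprD to T1E_1385 shaded. Of the 21 loci in the block 20 lie at 1.69 or higher in both treatments and T1E_1338 lies near 0.

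In T1E under the shock, the 4 tested tob loci rose and the same prophage block was high. The tob loci were put together after their values were seen, and are taken here as toluene dioxygenase loci. They lie near todX (T1E_4263) and todC1 (T1E_4266), but match neither the symbols nor the product terms of the fixed tod list. That list has 0 loci and 4 annotated-strand rows, with 0 calls, so its result does not cover the tob loci. The ring-cleavage dioxygenase locus tobE (T1E_4271, 4646320 to 4647201) went from 9.33 ± 4.43 to 358.4 ± 211.5 scaled read equivalents (SD, n = 2), a log2 change of 5.05 ± 0.45 (limma adjusted p = 0.000106). Ferredoxin gene tobB held 173 read equivalents in shock and 3 in glucose, a scaled ratio of 27.6 (exact 95% interval 9.3 to 135.3), and hydratase gene tobG 133 and 3, a ratio of 21.2 (7.1 to 104.3), with intervals that cover counting error only and not the larger spread between libraries. Acetaldehyde dehydrogenase gene tobI rose by 2.67 and the sensor kinase gene dhkD by 1.76. The loci tobB, tobG, dhkD and, below, glcA and T1E_1352/T1E_1353 fall outside the naming rule and were chosen after their values were seen. In all, 181 of 577 loci passed, 87 higher and 94 lower.

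In the prophage block 20 of 21 loci rose in shock too, by 1.69 to 3.57, including T1E_1352/T1E_1353 (3.57), T1E_1374/T1E_1375 (2.95), T1E_1344 (2.87) and T1E_1346/T1E_1347 (2.87), with T1E_1338 at 0.09. Hypothetical gene T1E_1884 rose by 2.98 ± 0.21, copper resistance gene T1E_4513 by 2.97 ± 0.38 and glycolate permease gene glcA, at 12.4 read equivalents on average, by 2.53. Falls were at T1E_0634 (-1.57), engA (-1.55), htpG (-1.44), ilvH (-1.37), yurJ (-1.33), ppa (-1.32), T1E_1832 (-1.29) and maeB (-1.27). Chaperone gene dnaK was at -1.22 ± 0.20 (limma adjusted p = 0.0018), clpX/clpP/tig at -0.83 and clpB at 0.25, which did not pass. TCA loci fell at 4 of 13, or 5 when adjusted over the list alone, with sucD/sucC/lpdG at -1.22. Their camera adjusted p was 0.00563, and the adjusted p = 0.666 with an estimated correlation. Ribosomal protein loci fell at 9 of 15, also 9 over the list alone, with the locus from rpsJ at -0.83, a camera adjusted p of 0.00613 and an adjusted p = 0.666 with an estimated correlation. Nitrogen loci fell at 4 of 6, with glnA at -1.05, but the list did not pass (camera adjusted p = 0.178). The atpI locus was at -0.93 and dksA at -1.23. Without glucose replicate 1 the count was 106, and without glucose replicate 2 it was 100, where dhkD no longer passed. The split was 48 higher and 169 lower with the authors' scaling, and 541 higher and 0 lower with scaling to all signal, where none of the falls named here was lower past the threshold and most turned into rises.

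**Figure D4:**
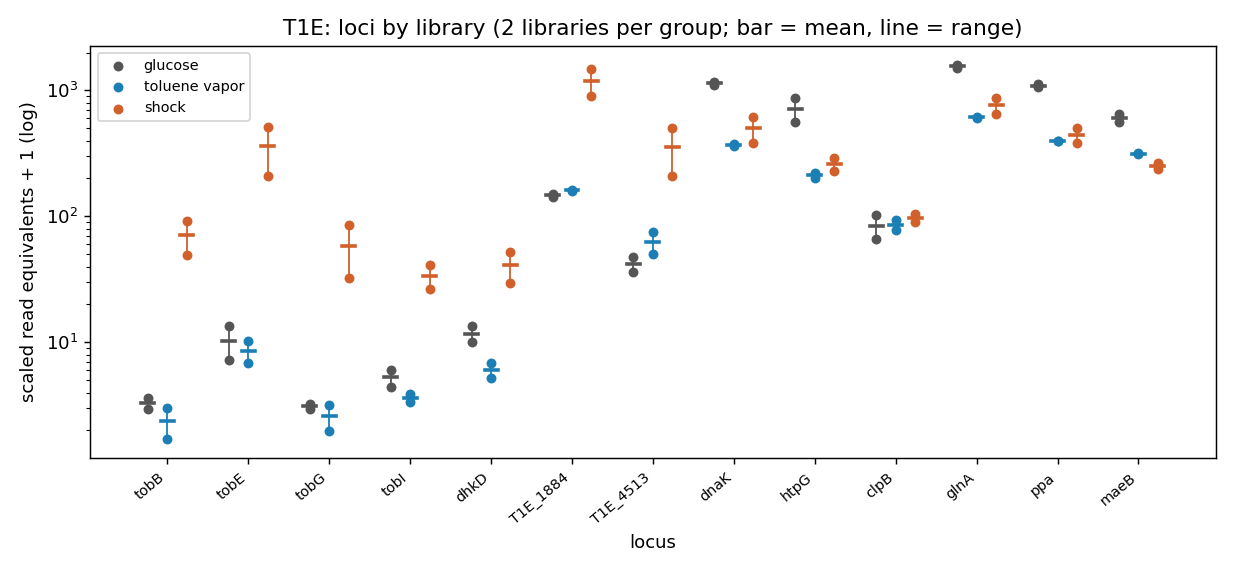
Scaled read equivalents plus 1 (log axis) at 13 T1E loci in glucose, toluene vapor and shock, 2 libraries per group, with the bar at the mean and the line over the range. At tobE the shock libraries average 358.4, the vapor libraries 7.59 and the glucose libraries 9.33, and at dnaK glucose averages 1137.0.

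Between shock and vapor in T1E, few loci differed, and the largest differences were at tobE, tobB and tobG. The tobE locus was higher in shock by 5.28 ± 0.45 on the log2 scale (limma adjusted p = 0.000144), tobI by 3.18 and dhkD by 2.72. For tobB the scaled ratio was 40.6 (exact 95% interval 15.6 to 150.7) and for tobG it was 31.2 (11.9 to 116.3), for counting error only. None of these tob loci passed in vapor against glucose, where tobE was at -0.23 and tobB at -0.53, but tobE did pass as higher there with scaling to all signal. T1E_1884 (2.85), T1E_4513 (2.40), T1E_1564 (2.25) and glcA (3.28) were also higher, while T1E_4422 (-1.12), T1E_1992 (-0.84) and ornithine decarboxylase gene ldc (-0.82) were lower. The periplasmic efflux gene sepA held 69 read equivalents in glucose and 1 in vapor, a scaled ratio of 135.2 (exact 95% interval for counting error only 23.5 to 5417.0), and was higher in shock than in vapor by 3.65. It was named after its values were seen. In all 15 of 577 loci passed, 11 higher and 4 lower, with 7 to 9 without any 1 glucose or vapor library and 73 without shock replicate 1. The authors' scaling gave 13 and 2, without T1E_1992 and ldc, and ldc passed under no other scaling.

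Vapor and shock changed many of the same loci in each strain, in the same direction. In KT2440 all 19 loci higher in vapor were higher in shock, and 18 of the 22 lower ones were lower. In T1E 64 were higher in both and 72 lower in both. Both comparisons use the same glucose libraries, and the number shared by chance under such controls was not simulated. No locus passed in opposite directions in either strain. Across loci, which are not independent replicates, the fold changes had a Pearson correlation of 0.72 in KT2440 and 0.732 in T1E, and Spearman values of 0.776 and 0.78. Simulated unchanged groups against shared controls gave 0.499 in both strains. The covariance was 1.775 against a simulated 0.08 in KT2440, and 0.5 against 0.028 in T1E. Every simulated group had the same spread at a locus. In KT2440, chi-square per degree of freedom between libraries was 53.0 in glucose, 12.3 in vapor and 11.8 in shock. A wider spread in shared controls raises the simulated values, so those for KT2440 may be too low. With a different glucose library for each comparison r was 0.572 and 0.637 in KT2440 and 0.615 and 0.683 in T1E. On annotated-strand rows r was 0.568 in KT2440 and 0.775 in T1E, and fell to 0.071 and to at most 0.055 with such split controls.

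**Figure D5:**
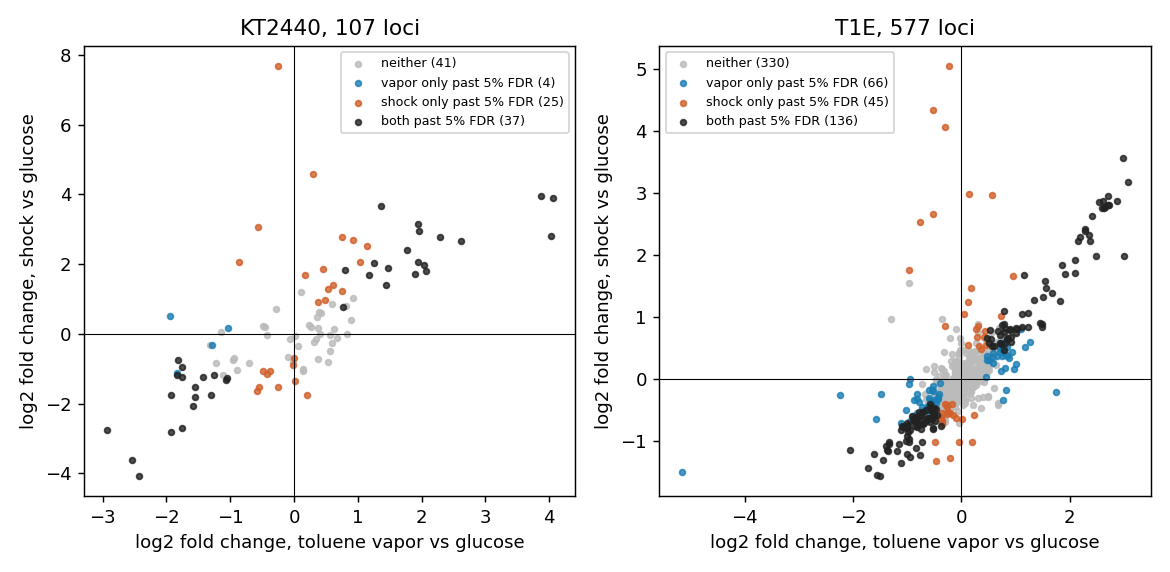
Log2 fold changes of loci for toluene vapor against glucose (x axis) and shock against glucose (y axis) in KT2440 (107 loci) and T1E (577 loci), with points coloured by which comparison passed a 5% false discovery rate. Both comparisons passed at 37 KT2440 loci and 136 T1E loci, shock alone at 25 and 45, and vapor alone at 4 and 66.

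Between strains, 45 pairs of loci share a gene symbol found once in each table, over 45 KT2440 and 29 T1E loci. Paired loci need not cover the same part of a gene. Glutamine synthetase locus glnA rose by 2.77 ± 0.52 in KT2440 shock and fell by 1.05 ± 0.15 in T1E shock. Locus lpdG, which covers 106 bases in KT2440, rose there by 1.84 ± 0.28, while the T1E locus sucD/sucC/lpdG fell by 1.22 ± 0.12. That T1E locus is also paired with KT2440 sucC, at -0.68 ± 0.41 in shock (limma adjusted p = 0.171), so its KT2440 partners did not move together. Under vapor infA fell by 2.54 ± 0.28 in KT2440 and was at 0.84 ± 0.21 in T1E (adjusted p = 0.0136). Of the 45 pairs 30 differed by 1 or more on the log2 scale in either treatment, 29 in vapor and 17 in shock. A single T1E locus, the one from rpsJ, takes part in 13 pairs, with 12 of the vapor and 4 of the shock differences, or 9 and 5 with the authors' scaling and 4 and 10 with scaling to all signal. Of pairs past the threshold in both strains, 3 of 8 in vapor and 5 of 13 in shock went the same way. With scaling to all signal glnA and sucD/sucC/lpdG did not fall in T1E shock. The 2 tables were normalized separately, so these differences of log2 changes were not tested. On annotated-strand rows 587 of 661 shared symbols differed by 1 or more. With a mean of 10 or more read equivalents in both strains 4 pairs were left, and all 4 differed.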

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

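All tests of explanations in this part were chosen after the result was seen, and only the prediction for phage DNA was written before its value was seen.

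Some loci moved in opposite directions in the 2 strains in every library, which was not tested as a difference. Of 45 pairs, 13 did so in vapor and 10 in shock. Those where both strains also passed a 5% false discovery rate are given as the log2 change in KT2440 minus that in T1E. Most rest on T1E falls against the median locus: with scaling to all signal 1 of these 5 pairs stayed opposite in vapor and 0 of 8 in shock. Another 3 and 5 pairs past the threshold in both strains went the same way. Over all loci, treated and glucose libraries did not overlap at 66.4% (KT2440) and 72.6% (T1E) in vapor, and 77.6% and 65.5% in shock. Across the 45 pairs the log2 changes of the strains had a Pearson correlation of -0.139 in vapor and 0.045 in shock. The number of opposite pairs that unrelated directions would give was not computed. In vapor, infA differed by -3.38, lpdG by 1.81, rpsH by 3.01, rpsN by 3.74 and secY by 2.56. In shock, clpX differed by 2.07, glnA by 3.82, lpdG by 3.06, oprL by 2.10, rpoD by 1.99, rpsH by 2.55, rpsN by 3.50 and secY by 2.22. The KT2440 loci rpsH, rpsN and secY are all paired with a single T1E locus of 28 genes, so they are not independent. The T1E locus paired with lpdG is also paired with KT2440 sucC (-0.94 in vapor, -0.68 in shock). The one paired with oprL is also paired with KT2440 tolB (0.31 in vapor, -0.23 in shock). Neither sucC nor tolB passed in KT2440, but in shock both had the sign of their T1E locus.

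Predicted transcripts opposite no annotated gene took no part in the comparisons, and many lay above the glucose level. With the scaling of the loci, in KT2440 40 of 57 were at least 2-fold higher in vapor without overlap between libraries and 5 lower, and in shock 44 and 3. In T1E 34 of 118 were higher in vapor and 5 lower, and in shock 28 and 6. These counts depend on scaling: with scaling to all signal they were 34 and 11, then 42 and 7 in KT2440, and 104 and 0, then 103 and 0 in T1E. Chance puts all libraries of 1 group above the other for about 1 in 6 features. In T1E, 17 rows of other RNA and any transcripts opposite them took no part in the comparisons either. Their signal counts in scaling to all signal, and its share was not computed.

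Signal opposite annotated genes was weighed against 3 explanations. Loss of strand in the libraries would give equal signal on both strands, but the lower of the strains' median ratios over loci was 18.3. Transcription antisense to the genes would leave rRNA and tRNA mostly on their own strand, but at least 98.88% of their signal lay opposite. An exchange of strands at a step before the tables is consistent with 99.1% of the 116 rRNA and tRNA genes that have an opposite transcript holding more signal there. The other 45 of 161 rows classed as rRNA or tRNA have no such transcript. They include T1E_3667, which carries the symbol rumA and was classed by its product text, so it may not be an rRNA gene. The value had been seen before the test was chosen. Genes that share a transcript each count its whole signal, so the 116 are not independent. No biological explanation was tested.

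The T1E prophage block was higher in both treatments. More phage DNA in the treated libraries would raise both strands alike. The block's annotated-strand signal rose against all gene rows by at most 1.61 on the log2 scale, between the bounds set. The block's loci are scaled to the median locus instead. The ratio of loci signal to gene rows fell from 14.8 and 13.2 in glucose to 6.5 to 8.3 in treated libraries. On the scale of summed loci signal the annotated-strand rise would therefore be larger. The bounds thus compare unlike scales and cannot decide, and more phage DNA cannot be told apart from more transcription. Scaling shifts all loci of a library alike, so it does not account for the rise relative to the loci on both sides, whose median change was -0.01 at most. Those flanking values are near 0 largely because the scaling centres the loci, so they cannot test a rise in absolute terms. With scaling to all signal the median of all loci was 1.36 in vapor and 1.40 in shock. The block's rise was present in each treated library against each glucose library, with the lowest of 8 differences at 2.11. All 202 T1E loci called in vapor and all 181 in shock had groups that did not overlap. The block was set around such rises, so this describes it and is not a separate test of a single library.

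Relative to the median locus, the tob loci of T1E were higher in shock and not in vapor. An exchange of 1 vapor and 1 shock library is argued against by the lowest shock library, which held 21.5 times the highest vapor library over these loci. Low depth is argued against too, since at the shock level the shallower vapor library would hold 470 read equivalents and it held 10.5. A difference in dose or time of exposure, or an exchange of whole groups, may be the source and was not tested. The solvent may differ too, as the shock is called toluene in the sample labels and butanol in the series design text.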

How the results depend on the processing

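The alternatives for loci were all chosen after seeing the data, and those for annotated rows before. Of 1606 values of named loci under settings other than scaling, 1550 kept their direction and side of the threshold, 54 lost and 2 gained a call. Of 978 with a library left out, 863 kept it, 111 lost and 4 gained a call, and in neither set did a called locus change direction. Of 489 under other scalings, 396 kept it, 60 lost and 9 gained a call and 24 changed direction, all with scaling to all signal. Moved to the median of the reported scaling, which removes most such changes by construction, 459 of the 489 kept it. Of the counts, 147 of 183 under other settings and 65 of 96 with a library left out stayed within 1.5 times. Where not said otherwise, the cause was not tested.

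With scaling to all signal these log2 changes turned. In T1E vapor the falls became 0.47 (clpX/clpP/tig), 0.01 (fda), 0.40 (sucD/sucC/lpdG), 0.46 (maeB), 0.29 (rpsJ locus), 0.53 (cmk/rpsA), 0.41 (atpI locus), 0.06 (glnA) and 0.65 (dksA). In T1E shock they became 0.21 (dnaK), 0.60 (clpX/clpP/tig), 0.06 (ilvH), 0.09 (yurJ), 0.11 (ppa), 0.12 (T1E_1832), 0.16 (maeB), 0.21 (sucD/sucC/lpdG), 0.60 (rpsJ locus), 0.50 (atpI locus), 0.38 (glnA), 0.20 (dksA), 0.85 (rpoD) and 1.01 (tolA/tolB/oprL). The rise at oprF in KT2440 vapor became 0.

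For shock against vapor at KT2440 loci, 20 became 33 with upper-quartile scaling, 11 with scaling to all signal and 41 with only the 4 libraries compared. In T1E, scaling to all signal, rRNA included, gave 520 (vapor), 541 (shock) and 26 (shock against vapor). Unmerged fragments gave 310 and 286, being more features, and a log2 change of at least 1 left 75 and 73. For shock against vapor, T1E gave 6 at a mean of 50 or more read equivalents and 7 with only the 4 libraries compared. The fits with other moderation gave, for vapor, shock and shock against vapor in KT2440, 53, 68 and 30 (trend and robust), 39, 62 and 17 (robust alone) and 39, 63 and 17 (neither). In T1E they gave 197, 179 and 12, then 164, 153 and 10, then 165, 155 and 10.

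Leaving out each library gave 18 to 55 loci for KT2440 vapor, 40 to 67 for shock and 6 to 42 between them, and 79 to 246 for T1E vapor, 100 to 215 for shock and 7 to 73 between them. The lone library of a group is then assumed to vary like the others.

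Annotated rows had 0 calls, but at a mean of 10 or more read equivalents 11, 13 and 1 in KT2440 and 3 in T1E vapor. With rRNA, tRNA and predicted rows kept T1E gave 221, 168 and 4, and with only the 4 libraries compared 1 for shock against vapor. A library left out gave 0 to 302, 0 to 351 and 0 to 295 in KT2440 and 0 to 1336, 0 to 1314 and 0 to 1 in T1E.

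The correlation of vapor and shock changes on annotated rows was 0.071 with either split of the glucose libraries in KT2440 and 0.018 or 0.055 in T1E, and 0.875 and 0.895 at a mean of 10 or more. At loci it was 0.572 and 0.637 (KT2440), 0.615 and 0.683 (T1E) with split controls and 0.813 in T1E at a mean of 50 or more. List tests went from 7 to 0 calls with an estimated correlation and to 13 with fry at loci, and from 2 to 0 and 0 on annotated rows. Strain differences on annotated rows went from 587 of 661 to 4 of 4 at a mean of 10 or more and to 323 where symbol and product both match, being fewer genes.

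No pairing by replicate number was seen: deviations of same-numbered libraries correlated at -0.37, -0.04 and -0.19 over KT2440 loci and at -0.14, -0.12 and -0.03 over T1E loci. The labels do not say whether libraries were paired, and these values cannot exclude a pairing that the numbers do not follow. With the replicate block 44, 57 and 18 loci passed in KT2440 and 196, 179 and 19 in T1E, with 0 calls on annotated rows, 7 list calls at loci and 2 on annotated rows, and 587 and 30 strain differences. With the numbers of 1 group crossed, 45, 63 and 20 passed in KT2440 and 211, 181 and 19 in T1E.

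DESeq2 and limma-voom, listed beforehand, were not run because the tables hold no read counts, and alternatives for 1 value per condition do not apply.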

Other observations

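The gene T1E_4264 encodes a hypothetical protein on the minus strand (4641017 to 4641220), between todX and todF, which lie on the plus strand. It was picked after its values were seen. Its annotated-strand signal was 118.45 and 99.01 read equivalents in the shock libraries, against 0.7 and 0 in glucose and 1.04 and 1 in vapor. On the gene-row test its log2 change in shock was 8.65 ± 2.09, with a limma adjusted p of 0.249. This signal lies on the same strand as that of the neighbouring tob loci.

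The KT2440 transcript opposite no gene with the most signal lies at 5390008 to 5390384 and held 48290 read equivalents on average, 35.4% of the signal of such transcripts. In T1E the first such transcript lies at 5678975 to 5680103 with 191929 read equivalents, 73.5% of that signal.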
